A study of Rattus norvegicus with 6 samples.

How the data were processed

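Total RNA from knee articular cartilage was extracted with TRIzol and made into libraries from 1 µg per sample with a Hieff NGS Ultima Dual-mode mRNA kit, per the labels' protocols. The 6 libraries were 3 from control and 3 from loaded knees. The deposited table held raw read counts per gene, whole numbers that the authors left unnormalised, per the file headers and the values. It also held FPKM values, which per the file headers the authors computed per library, and the authors' own DESeq2 comparison as a false discovery rate (p-value scale) and a log2 fold change. The submitters' processing notes name HISAT2 and DESeq2 without versions and the mouse build mm10. The gene identifiers in the table are rat Ensembl identifiers, so the build that was aligned to is uncertain, and no coordinates are given. The counting tool, annotation release, strand setting and any pooling are not given in the sources used here. Without a known strand setting, reads of a gene and an overlapping antisense gene cannot be told apart, and near-identical gene copies may share reads.

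The table had 26991 lines, of which 10 were spilled pieces of over-long annotation cells and were dropped, leaving 26981 features (22050 Ensembl genes and 4931 features that the authors named as new genes). Symbols were taken from the table, 10 symbols that a spreadsheet had turned into dates were not used as names, and 220 rows shared a symbol with another row and were kept by identifier. Of 800 listed symbols in the gene lists, 781 matched a gene, 7 of them through an older symbol in a RefSeq gene table of assembly GRCr8. No column was left without a sample.

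Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the group (16447 kept, 10534 left out), libraries were scaled with TMM (factors 0.961 to 1.05), and loaded was compared with control by the robust quasi-likelihood F test without a replicate block. The threshold was a Benjamini-Hochberg adjusted p under 0.05. CPM values use TMM-scaled library sizes, and SE is the log2 fold change divided by the square root of F. Gene lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, and adjusted over the 41 lists, with an estimated correlation and fry as alternatives. Similarity used log2 CPM with a prior count of 2. With 3 libraries against 3, an exact permutation test cannot give a two-sided p below 0.1, so no single-gene permutation test is given.

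The groups, tests, 41 gene lists and the rule for named genes were fixed before the data were examined. The rule takes the 10 largest rises and 10 largest falls among called genes with non-overlapping groups, a mean of at least 5 CPM in the higher group and a proper symbol. It adds up to 4 called members of each list with the smallest adjusted p, and 16 genes of cartilage, proteases, cytokines and mechanosensing whatever their result. Other list members named in the text were chosen after their values were seen: the members that moved against their list, and Ihh, Panx3, Timp3, Scrg1 and Cnmd. Some genes that the rule takes are not reported here. Members shared by lists, such as Ibsp and Alpl in the hypertrophic and osteoblast lists, count in each.

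The lists were named for cartilage matrix, superficial zone, hypertrophic cartilage, proteoglycan synthesis, proteases and their inhibitors, bone, fibrous and tendon cells, synovium, blood and immune cells, vessels, muscle, fat and nerve, and for signalling, stress and metabolic pathways. Tissue and blood cell lists were included because dissected cartilage can hold other cell types.

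The pipeline was tested on counts simulated for the loaded against control comparison over 16447 genes. The edgeR test recovered 18% of 50 genes changed 1.25-fold, 78% of 50 at 1.5-fold, 90% of 50 at 2-fold and 100% of 50 at 4-fold, and called 20 of 16247 unchanged genes. Camera called 0 of 40 unchanged lists and called the raised list. Changed genes and members of the raised list were drawn from genes with a mean count of at least 50. All genes were simulated independently, so the simulation does not test camera on lists with correlated members. In the real libraries the estimated correlation of a list reached 0.459.

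Alternatives were DESeq2 1.42.0 (with camera on its Wald statistics), limma-voom with and without sample quality weights, size factors of the DESeq2 type, upper-quartile scaling, library totals, no filter, a stricter filter (at least 1 CPM in 3 libraries), each library left out, a replicate block, abundant lists left out, and thresholds of 0.01 and 0.1. Chosen after seeing the data were leaving out both replicate 2 libraries, leaving out the new-gene and AABR features, and the thresholds of the deposited table. FPKM values entered no test.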

Results

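RNA from the articular cartilage of the right knee was sequenced in male Sprague-Dawley rats that were 6 weeks old when the experiment began. The experiment held 70 rats randomised to 7 groups, and RNA was sequenced from an unloaded control group and from 1 loaded group, with 3 libraries each. In the loaded group a materials-testing machine compressed the right knee and ankle along the axis of the limb under anaesthesia, every 2 days for 4 weeks. Each session had 40 cycles, and in each 10 s cycle the limb was held at 5 N for 9 s and raised to a peak of 20 N for 0.5 s. The loaded libraries carried a label naming excessive mechanical load without its size. The peak of 20 N and the 4 weeks come from the study design. The control libraries were identified by their titles and by the unloaded group of 3 in the study design. The labels do not say that each library came from a separate rat, so the p-values measure the spread between these libraries, which may in part be technical. The comparison asks which transcripts differ between loaded and control knee cartilage in a model of load-induced osteoarthritis.

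Library totals were 36360349, 34527264 and 40332904 counts in control 1 to 3 and 29847274, 28435307 and 33616096 counts in loaded 1 to 3. At these depths a count of 0 in a library allows a level of up to 0.0744 to 0.106 CPM, a limit that covers counting error only. Between 18647 and 19541 genes had at least 1 count in a library. The correlation of log2 CPM was 0.985 to 0.988 between control libraries, 0.972 to 0.977 between loaded libraries and 0.955 to 0.959 between a control and a loaded library. The first principal component, with 52.6% of the variance, separated the groups, and the second, with 16.7%, separated the loaded libraries from each other. No pair of libraries was identical, since the mean chi-square per gene was 7.24 or more for every pair. Abundant genes can dominate this mean, so it cannot show that typical genes varied beyond sampling noise.

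Transcripts of blood and marrow took a larger part of every library than those of cartilage. The erythroid list took 14.4% ± 0.601 of counts in control and 13.7% ± 0.591 in loaded libraries (SD, n = 3 each), and the neutrophil and marrow myeloid list took 5.86% ± 0.193 and 4.33% ± 0.332. The monocyte and macrophage list took 1.72% ± 0.0453 and 1.35% ± 0.0462, most of it Lyz2 (15060 ± 213 and 10740 ± 117 CPM), and as a list it did not pass (8 rose and 9 fell of 20). By contrast, the cartilage matrix list took 0.215% ± 0.0084 in control and 0.318% ± 0.0142 in loaded libraries. The skeletal muscle list stood at 0.922% ± 0.0127 and 2.30% ± 0.0113, the osteoblast and osteocyte list at 0.246% ± 0.00627 and 0.545% ± 0.0142, and the adipocyte list at 0.0615% ± 0.00114 and 0.0502% ± 0.00187. For the last 4 of these lists, and for the neutrophil and monocyte lists, all 3 loaded libraries lay on 1 side of all 3 control libraries.

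**Figure D1:**
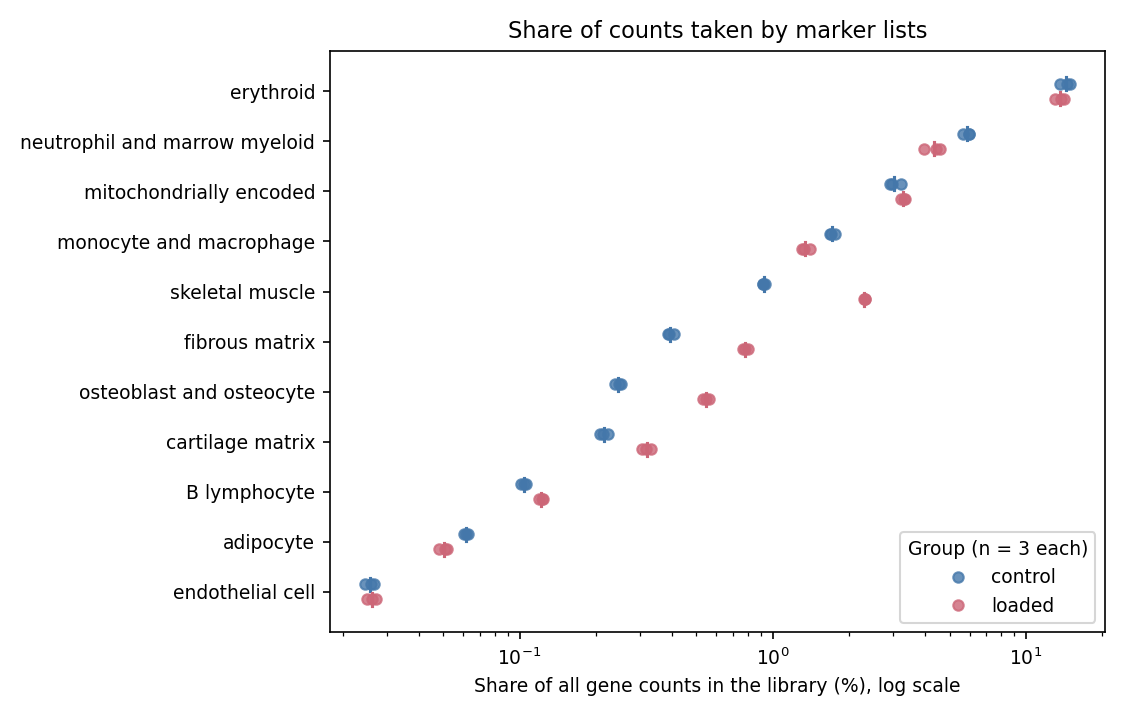
Share of all gene counts in each library, in percent on a log scale, taken by 11 marker lists. Points are the 3 control and 3 loaded libraries and ticks are group means. Erythroid transcripts took 14.4% and 13.7% of counts in control and loaded libraries, cartilage matrix transcripts 0.215% and 0.318%, and skeletal muscle transcripts 0.922% and 2.30%.

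Loaded knees carried more transcripts of interferon-induced, skeletal muscle, bone and collagen matrix genes, and fewer of adipocyte, neutrophil and marrow myeloid, cell cycle and sterol synthesis genes. As lists these passed at camera's preset correlation and none passed with an estimated one (lowest adjusted p = 0.074). The libraries mixed tissues and CPM is a relative measure. Whether the lower cell cycle and sterol synthesis lists follow from the lower marrow myeloid share was not tested. Of 16447 genes tested, 5895 (35.8%) changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2941 rising and 2954 falling. Of these, 1084 changed at least 2-fold, and 820 of the 1084 rose (75.6%) against 264 that fell. The 3 loaded libraries lay entirely above or below the 3 control libraries for 7870 genes (47.9% of those tested, where chance gives 10%). With library totals in place of the TMM scaling, 3578 genes rose and 2074 fell, so that 63.3% of calls were rises against 49.9% with TMM. The common biological coefficient of variation was 0.137. In the authors' deposited table, made with DESeq2, 670 genes were called up and 176 down at a false discovery rate of 0.01 and a 2-fold change. At the same thresholds 670 rose and 197 fell here, and the 784 genes called in both went the same way.

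The genes in this paragraph are the 10 that the naming rule takes for the largest rises. Ifit1, an interferon-induced antiviral gene, rose from 25.8 ± 0.902 to 253 ± 7.11 CPM (SD, n = 3 each), a 9.82-fold rise (adjusted p = 7.38e-15, edgeR). Oncostatin M (Osm), an interleukin-6 family cytokine, rose from 10.9 ± 0.165 to 104 ± 6.51 CPM, and Rtp4, another interferon-induced gene, from 7.59 ± 0.466 to 63.2 ± 3.22 CPM. The immune receptor genes Lilrb3 and Sirpd rose by 3.85 ± 0.158 and 3.36 ± 0.141 on the log2 scale (± SE). The transcription factor gene Tbx1 rose by 3.31 ± 0.204, the ectonucleotidase gene Entpd3 by 3.48 ± 0.249 and Lrrc30 by 3.90 ± 0.327. Dr1, a subunit of a transcriptional repressor, and Cldn5, an endothelial tight junction gene, had the 2 largest fitted changes, 6.69 ± 0.756 and 5.16 ± 0.985, but both were near the floor in the controls. Dr1 had 4, 6 and 18 counts there and 1057, 980 and 438 counts in the loaded libraries. Cldn5 had 15, 0 and 0 counts in the controls and 165, 118 and 204 in the loaded libraries, and without control 1, where both remaining controls were at 0, its fitted change was 10.40 and depends on the prior count. Dr1 lost its call with voom (adjusted p = 0.13), with voom and quality weights (adjusted p = 0.0712) and without both replicate 2 libraries (adjusted p = 0.0603) but in none of the other alternatives.

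Among the largest falls were the serine protease gene Prss29, from 91.3 ± 1.92 to 4.90 ± 0.379 CPM, an 18.6-fold lower level (adjusted p = 7.38e-15, edgeR), and the lysozyme gene Lyc2, from 379 ± 17.7 to 35.4 ± 3.83 CPM. Adiponectin (Adipoq), a hormone of fat cells, went from 54.0 ± 1.62 to 13.3 ± 2.42 CPM, and Pck1, a gluconeogenesis enzyme also active in fat, from 13.8 ± 0.311 to 3.08 ± 0.612 CPM. Stab2, a scavenger receptor of sinusoidal endothelium, fell by 1.88 ± 0.144 on the log2 scale (± SE). The glutathione transferase gene Gstt3 fell by 2.66 ± 0.217, Syt15 by 2.23 ± 0.204, Tsbp1 by 2.18 ± 0.195, Mboat2 by 2.00 ± 0.296 and Nnat by 1.99 ± 0.23. Lyc2 belongs to a family of near-identical lysozyme genes, and Prss29 to a cluster of related mast cell proteases, so reads may be split between copies.

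Of 41 gene lists, 18 passed the competitive test camera at a preset correlation of 0.01, 11 upward and 7 downward. None passed with the correlation estimated per list, where the lowest adjusted p was 0.074 and 13 lists had an unadjusted p under 0.05, and the rotation test fry, which asks only whether members move on balance one way, called 31. Each list below has its adjusted p from camera and then its adjusted p with an estimated correlation.

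**Figure D2:**
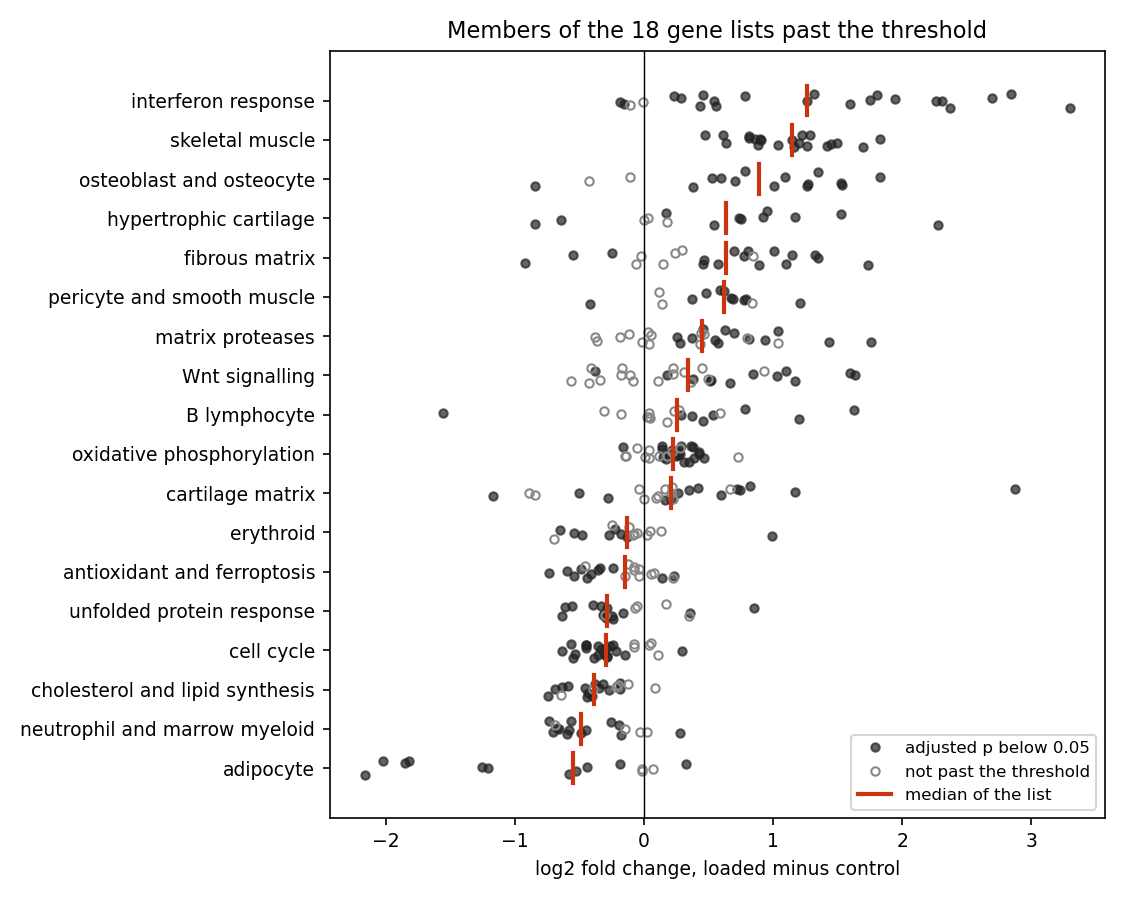
Log2 fold change (loaded minus control) of every tested member of the 18 gene lists that passed camera at the preset correlation. Filled points passed an adjusted p under 0.05 in edgeR, open points did not, and red bars are list medians. The interferon list had the highest median (1.26) and the adipocyte list the lowest (-0.55).

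Interferon response genes were higher in the loaded knees. Of 23 tested members 19 rose and 2 fell (22 changed when adjusted over the list alone), with a median log2 fold change of 1.26 and a camera adjusted p of 4.9e-10 (adjusted p = 0.0736 with an estimated correlation). Irf7, the transcription factor that amplifies type I interferon signalling, rose from 94.4 ± 3.09 to 467 ± 21.3 CPM. Ifit3 rose from 45.3 ± 1.86 to 326 ± 5.83 CPM, and the ubiquitin-like modifier Isg15 from 16.1 ± 1.24 to 83.1 ± 3.45 CPM. The members that fell, the immunoproteasome subunit Psmb9 and the transcription factor Irf1, moved by -0.16 and -0.19. Proinflammatory mediators as a list did not pass (6 rose and 6 fell of 21, 12 adjusted over the list alone, adjusted p = 0.696). Within it Ptgs2, the inducible cyclooxygenase, rose from 1.94 ± 0.38 to 7.63 ± 1.58 CPM, lipocalin 2 (Lcn2) rose by 0.32 ± 0.0315 (log2 ± SE), and Tnf fell from 3.79 ± 0.449 to 0.538 ± 0.219 CPM. Il1b fell by 0.22 ± 0.0746 (adjusted p = 0.029, edgeR), a call lost with library totals, without control 1, control 2 or loaded 3, and without both replicate 2 libraries (adjusted p = 0.0601 to 0.169). Il6 had 0 to 6 counts per library and was below the count filter.

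Genes of the cartilage matrix rose on balance. Of 25 tested members 11 rose and 3 fell (15 changed when adjusted over the list alone), with a median of 0.21 and a camera adjusted p of 0.0155 (adjusted p = 0.15 with an estimated correlation). Type II collagen (Col2a1, ENSRNOG00000058560), the main fibril of cartilage, rose from 1006 ± 40.6 to 1519 ± 45.2 CPM, a log2 fold change of 0.59 ± 0.0367 (SE). The large proteoglycan aggrecan (Acan) rose from 47.8 ± 1.4 to 63.7 ± 5 CPM and Comp, a cartilage glycoprotein, from 134 ± 3.71 to 225 ± 7.18 CPM. Type XI collagen genes Col11a1 and Col11a2 rose by 0.82 ± 0.0459 and 0.72 ± 0.0403, and Matn4 by 2.87 ± 0.152. The members that fell were Cytl1 (-1.17 ± 0.08), Scrg1 (-0.51 ± 0.15) and Cnmd (-0.28 ± 0.06). Sox9, the master transcription factor of chondrocytes, stood at 1.35 ± 0.0766 and 2.14 ± 0.76 CPM (adjusted p = 0.106, edgeR) and passed without loaded 1 (adjusted p = 0.032). Genes of the surface zone went both ways (3 rose and 3 fell of 13, 6 adjusted over the list alone, adjusted p = 0.853). Lubricin (Prg4, ENSRNOG00000002385), which coats the joint surface, fell from 112 ± 5.75 to 59.99 ± 4.81 CPM, and Thbs4 fell from 63.2 ± 1.82 to 29.5 ± 0.966 CPM, whereas Cilp2 and Dpt rose by 0.44 ± 0.0812 and 0.40 ± 0.0912. Enzymes of proteoglycan synthesis showed few calls (2 rose and 3 fell of 20, 3 adjusted over the list alone, adjusted p = 0.68). Chsy1 rose by 0.57 ± 0.0576 and Papss1 fell by 0.43 ± 0.0483, while the call of Xylt2 (-0.20, adjusted p = 0.0463) was lost in most alternatives.

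Genes of hypertrophic cartilage, the zone that precedes mineralisation, were raised. Of 14 tested members 9 rose and 2 fell (11 adjusted over the list alone), with a median of 0.64 and a camera adjusted p of 0.000849 (adjusted p = 0.116 with an estimated correlation). Type X collagen (Col10a1, ENSRNOG00000051399), the marker collagen of hypertrophic chondrocytes, rose from 20.8 ± 2.34 to 101 ± 6.57 CPM, 4.85-fold. Indian hedgehog (Ihh), Panx3 and the parathyroid hormone receptor Pth1r rose by 1.17 ± 0.18, 0.95 ± 0.11 and 0.92 ± 0.0646. Alkaline phosphatase (Alpl) fell from 229 ± 11.1 to 128 ± 6.12 CPM, and Runx3 also fell. The collagenase Mmp13 stood at 838 ± 6.85 and 857 ± 15.1 CPM (adjusted p = 0.479, edgeR), with a call only when library totals replaced the scaling (adjusted p = 0.0362).

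Bone and fibrous matrix genes rose with them. In the osteoblast and osteocyte list 13 of 16 members rose and 1 fell (14 adjusted over the list alone; median 0.89, camera adjusted p = 2.78e-05, adjusted p = 0.103 with an estimated correlation). Bone sialoprotein (Ibsp) rose from 173 ± 5.41 to 500 ± 19.2 CPM, type I collagen (Col1a1) from 1522 ± 40.5 to 3872 ± 72.1 CPM, and osteomodulin (Omd) from 3.89 ± 0.506 to 13.8 ± 1.26 CPM. In the fibrous matrix list 13 of 22 rose and 3 fell (17 adjusted over the list alone; median 0.64, camera adjusted p = 3.85e-05, adjusted p = 0.116 with an estimated correlation). Col1a2 rose from 711 ± 30.1 to 1776 ± 79.4 CPM and the crosslinking enzyme Lox from 9.99 ± 0.522 to 33.3 ± 0.489 CPM, whereas fibronectin (Fn1) fell from 756 ± 9.77 to 399 ± 9.24 CPM. Osteoclast genes did not pass as a list (5 rose and 2 fell of 14, 8 adjusted over the list alone, adjusted p = 0.14). The proton pump subunit Atp6v0d2 and tartrate-resistant phosphatase (Acp5) rose by 1.15 ± 0.0922 and 0.64 ± 0.0409. Mmp9 and Ctsk, given below with the proteases, are also on this list and rose by 1.43 ± 0.0374 and 0.70 ± 0.0368. The list took 0.106% ± 0.000902 of counts in control and 0.189% ± 0.00756 in loaded libraries. The tendon and ligament list did not pass (1 rose and 3 fell of 8, 5 adjusted over the list alone, adjusted p = 0.219), in which Kera fell by 1.40 ± 0.171 and Tnmd fell by 1.11 ± 0.176.

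Among matrix proteases 13 of 26 rose and none fell (14 adjusted over the list alone; median 0.45, camera adjusted p = 0.000156, adjusted p = 0.122 with an estimated correlation). The gelatinase Mmp9 rose from 198 ± 2.07 to 534 ± 9.33 CPM and cathepsin K (Ctsk), the collagenase of osteoclasts, from 399 ± 10.2 to 647 ± 13.7 CPM. Both are also members of the osteoclast list, and which cells their transcripts came from was not tested. Mmp2 and Mmp14 rose by 0.82 ± 0.0643 and 0.93 ± 0.0756. Adamts5, an aggrecanase, rose from 1.57 ± 0.231 to 3.23 ± 1.1 CPM (adjusted p = 0.00786, edgeR), and without loaded 1 the change was 0.72 and missed the threshold (adjusted p = 0.0564). Levels of the aggrecanase Adamts4 were 2.35 ± 0.124 and 1.80 ± 0.654 CPM (adjusted p = 0.32) and those of stromelysin Mmp3 were 4.197 ± 0.919 and 3.26 ± 0.751 CPM (adjusted p = 0.236, edgeR for both). Protease inhibitors split (4 rose and 4 fell of 11, 9 adjusted over the list alone, adjusted p = 0.696), with Timp1 up by 1.27 ± 0.0778 while Timp3 fell by 0.96 ± 0.12.

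**Figure D3:**
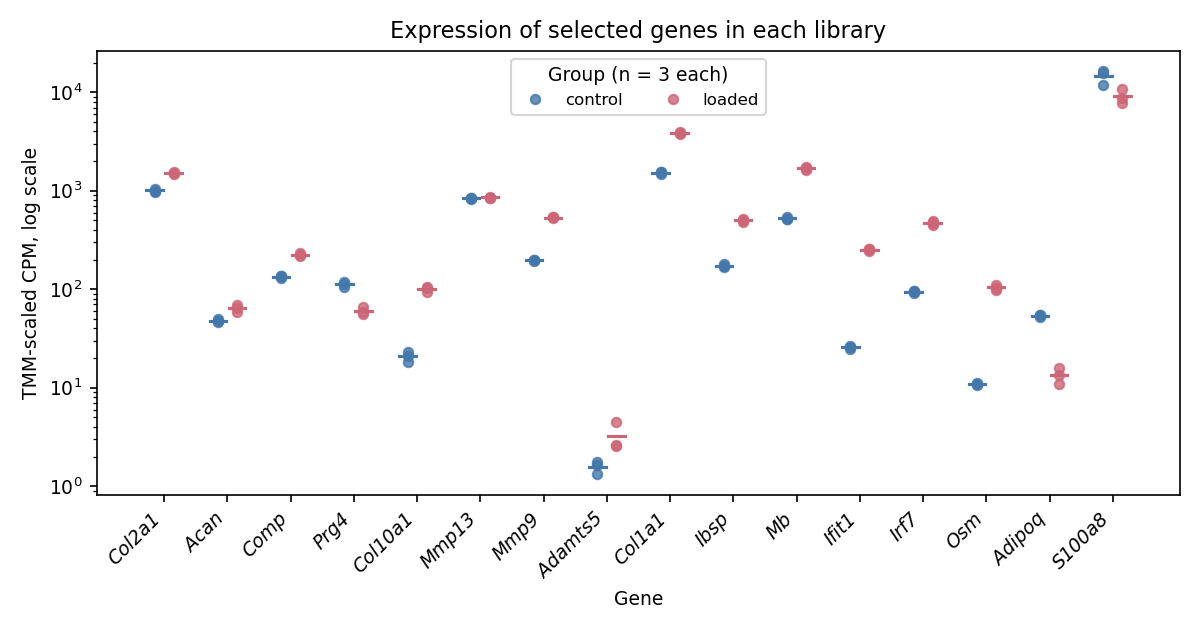
TMM-scaled CPM, on a log scale, of 16 genes in each of the 3 control and 3 loaded libraries, with group means as bars. Col10a1 rose from 20.8 to 101 CPM and Ifit1 from 25.8 to 253 CPM, Prg4 went from 112 to 59.99 CPM, and Mmp13 stood at 838 and 857 CPM.

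All 21 skeletal muscle genes rose (21 adjusted over the list alone), by 0.47 to 1.83 with a median of 1.14 (camera adjusted p = 6.43e-17, adjusted p = 0.103 with an estimated correlation). Myoglobin (Mb), the oxygen store of muscle, rose from 524 ± 13.3 to 1699 ± 57.2 CPM, skeletal actin (Acta1) from 1878 ± 23.2 to 4587 ± 150 CPM and Mybpc1 from 137 ± 3.72 to 486 ± 14.3 CPM. Pericyte and smooth muscle genes rose in 9 of 13 cases with 1 fall (11 adjusted over the list alone; median 0.62, camera adjusted p = 0.000306, adjusted p = 0.15 with an estimated correlation), among them Des and Synpo2, which skeletal muscle also expresses, by 0.79 ± 0.0464 and 1.21 ± 0.115. Nuclear genes of oxidative phosphorylation rose slightly, 20 of 32 with 1 fall (24 adjusted over the list alone; median 0.23, camera adjusted p = 0.000306, adjusted p = 0.415 with an estimated correlation), for example Atp5po by 0.39 ± 0.0467. Adipocyte genes fell, 10 of 14 with 1 rise (11 adjusted over the list alone; median -0.55, camera adjusted p = 0.00119, adjusted p = 0.116 with an estimated correlation). Beside Adipoq and Pck1, the lipid droplet gene Cidec went from 10.3 ± 1.41 to 2.95 ± 0.978 CPM.

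Several lists were lower. In the neutrophil and marrow myeloid list, which mixes genes of precursors and of mature cells, 12 of 17 fell and 1 rose (15 adjusted over the list alone; median -0.48, camera adjusted p = 2.78e-05, adjusted p = 0.152 with an estimated correlation). The granule protease genes Ctsg and Prtn3 fell by 0.56 ± 0.0306 and 0.70 ± 0.0414, and the member that rose, Mmp8, moved by 0.28. Cell cycle genes fell in 19 of 25 cases with 1 rise (20 adjusted over the list alone; median -0.29, camera adjusted p = 2.78e-05, adjusted p = 0.116 with an estimated correlation), for example Top2a, the replication topoisomerase, by 0.57 ± 0.0439. None of the 20 tested genes of cholesterol and lipid synthesis rose and 14 fell (15 adjusted over the list alone; median -0.39, camera adjusted p = 1.8e-05, adjusted p = 0.15 with an estimated correlation). Fdps, which makes farnesyl diphosphate, went from 82.3 ± 0.19 to 51.1 ± 1.48 CPM and the fatty acid desaturase gene Scd from 26.1 ± 1.52 to 15.6 ± 1.01 CPM. In the unfolded protein response list 12 of 19 fell and 2 rose (15 adjusted over the list alone; median -0.29, camera adjusted p = 0.00936, adjusted p = 0.146 with an estimated correlation). Chaperone-related Creld2 fell by 0.56 ± 0.0543, and the transcription factors Atf4 and Ddit3 rose by 0.36 ± 0.0392 and 0.85 ± 0.0913. Antioxidant genes fell in 9 of 21 cases with 2 rises (13 adjusted over the list alone; median -0.15, camera adjusted p = 0.0216, adjusted p = 0.353 with an estimated correlation), among them heme oxygenase (Hmox1) by 0.59 ± 0.0524, and without loaded 2 the median was -0.26.

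Markers of other blood cells moved less uniformly. B lymphocyte genes rose in 7 of 18 cases with 1 fall (8 adjusted over the list alone; median 0.25, camera adjusted p = 0.0185, adjusted p = 0.15 with an estimated correlation), among them the surrogate light chain genes Vpreb2 and Igll1, up by 1.62 ± 0.0971 and 0.78 ± 0.0851. Erythroid genes fell in 7 of 17 cases with 1 rise (8 adjusted over the list alone; median -0.13, camera adjusted p = 0.033, adjusted p = 0.353 with an estimated correlation), a call lost with library totals, with a stricter filter and without loaded 1 (adjusted p = 0.0506 to 0.0901). Monocyte and macrophage genes rose in 8 and fell in 9 of 20 cases (17 adjusted over the list alone, adjusted p = 0.804), in which Cd14 fell by 1.14 ± 0.0714 and Itgam fell by 0.73 ± 0.0464. T lymphocyte and NK genes had 1 rise and 2 falls among 17 (3 adjusted over the list alone, adjusted p = 0.696). Complement genes had 3 rises and 7 falls among 19 (10 adjusted over the list alone, adjusted p = 0.221), with C1qa up by 0.69 ± 0.0449 while C3 fell by 0.75 ± 0.0403.

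Signalling lists passed only for Wnt, where 11 of 28 rose and 1 fell (13 adjusted over the list alone; median 0.34, camera adjusted p = 0.0332, adjusted p = 0.15 with an estimated correlation). The members that rose included the Wnt antagonists Sfrp4, Frzb and Sfrp2, by 1.03 ± 0.0734, 1.10 ± 0.141 and 0.84 ± 0.122. The list's call was lost with DESeq2, library totals, a stricter filter, and without control 3 or loaded 2 (adjusted p = 0.0547 to 0.104). TGF-beta and BMP signalling genes had 8 rises and 4 falls among 26 (12 adjusted over the list alone, adjusted p = 0.416), in which Id1 fell by 0.75 ± 0.059. Mechanosensing and YAP target genes had 6 rises and 5 falls among 21 (11 adjusted over the list alone, adjusted p = 0.666). The stretch-activated channel gene Piezo1 fell from 47.5 ± 0.823 to 34.3 ± 1.69 CPM, the YAP target Ankrd1, which muscle also expresses, rose by 2.96 ± 0.137, and the channel gene Trpv4 stood at 2.67 ± 0.412 and 3.51 ± 1.19 CPM (adjusted p = 0.236, edgeR).

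The other lists did not pass camera. Counts of rises and falls were 10 and 5 of 23 for immediate early genes (15 adjusted over the list alone, adjusted p = 0.219), 6 and 2 of 13 for heat shock (8, adjusted p = 0.253), 6 and 12 of 26 for hypoxia and glycolysis (19, adjusted p = 0.188), and 2 and 6 of 13 for mitochondrially encoded genes (8, adjusted p = 0.126). They were 4 and 8 of 19 for apoptosis and pyroptosis (13, adjusted p = 0.334), 6 and 5 of 20 for autophagy (13, adjusted p = 0.944), 3 and 7 of 14 for senescence (11, adjusted p = 0.68) and 3 and 3 of 16 for the circadian clock (6, adjusted p = 0.696). They were 5 and 4 of 13 for synovial lining and fibroblasts (9, adjusted p = 0.721), 3 and 4 of 15 for endothelial cells (8, adjusted p = 0.975), 2 and 2 of 8 for nerve and Schwann cells (4, adjusted p = 0.853) and 0 and 1 of 9 for pain and neurotrophins (1, adjusted p = 0.268). The first number in each parenthesis is the count adjusted over the list alone. Median and mean had opposite signs for the heat shock, senescence, clock, nerve, autophagy and endothelial lists. The cyclin-dependent kinase inhibitor Cdkn1a (p21), a member of the senescence list, rose by 1.32 ± 0.102.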

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

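Of the 178 tested genes that the naming rule chose, 173 were called, 165 of these in every setting that tested them (18 settings, or 17 for 12 erythroid, muscle and mitochondrial genes), and neither these 173 nor the 18 called lists changed direction in any alternative. Genes named outside that rule were not rerun. With the preset correlation 16 of the 18 called lists were kept in every setting that tested them (18 settings, or 17 for skeletal muscle), the exceptions being the erythroid (17 settings) and Wnt lists, and 9 lists that had not passed changed the sign of their median in 31 cases. Over all alternatives, named genes missed the threshold in 33 cases and newly passed it in 2, and lists did so in 26 and 3, of which the osteoclast, immediate early and mitochondrially encoded lists passed with DESeq2. Leaving out each library in turn gave 4645 to 5614 changed genes, 982 to 1154 changed at least 2-fold and 17 to 18 lists. The number of lists depended on the set test: 0 with camera and an estimated correlation, 31 with directional fry and 41 with mixed fry. Fry compares no list with other genes. The estimated correlation lay below the preset 0.01 for the interferon (-0.0047), osteoblast and osteocyte (-0.0162) and hypertrophic cartilage (-0.028) lists. It also lay below 0.01 for the adipocyte (-0.0207), unfolded protein response (-0.0199), B lymphocyte (-0.0176), Wnt (-0.00394) and cartilage matrix (0.00105) lists. A higher correlation among members is therefore not why any of these lists were lost. For the remaining called lists the estimate lay above the preset, up to 0.307 for oxidative phosphorylation. Why the estimated setting kept no list was not tested. The highest correlation between a control and a loaded library moved from 0.959 at a prior count of 2 to 0.948 at 0.5 and 0.971 at 10, since the prior damps low counts. Deviations from the group means showed little correlation between same-numbered libraries (-0.014, 0.046 and 0.021). Both replicate 2 libraries nevertheless share 18 raised features and new-gene shares of 2.429% and 2.421%, against 1.77 to 1.947% in the others. Their chi-square per gene, 77.6, was the lowest between the groups, where the other pairs had 90.9 to 102. Something shared by the replicate 2 libraries is therefore not excluded. With the replicate block 5349 genes, 1012 genes at least 2-fold and 18 lists were called. Among alternatives chosen after seeing the data, leaving out both replicate 2 libraries gave 4751 genes, 1055 at least 2-fold and 18 lists, and leaving out new-gene and AABR features gave 5260, 747 and 18. Depth limits genes near the floor, such as Dr1, Cldn5 and Il6.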

Other observations

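The tests in this part were chosen after the results had been seen. In an exploratory camera test over the pathway and process annotations that the deposited table carries, 6 KEGG pathways and 9 biological processes passed at the preset correlation, and with an estimated correlation the adjusted p of these was 0.69 to 0.983. Muscle and heart terms made up 6 of the 9 processes, the strongest being muscle contraction, in which 25 of 31 genes rose and 1 fell (adjusted p = 1.57e-08), and the KEGG pathway cardiac muscle contraction passed as well. Steroid biosynthesis fell, 10 of 17 genes with none rising (adjusted p = 0.00598), as did DNA replication, 22 of 43 with 2 rising (adjusted p = 0.0117), and N-glycan biosynthesis, 22 of 58 with 3 rising (adjusted p = 0.04). Collagen fibril organization rose, 17 of 30 genes with 2 falling (adjusted p = 0.00145), as did cellular response to interferon-beta, 18 of 29 with 5 falling (adjusted p = 0.00365).

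Granulocyte genes outside the fixed lists were picked after their values were seen and not tested as a group. The eosinophil granule genes Prg2 and Epx rose from 1449 ± 79.7 to 2551 ± 67.9 CPM and from 373 ± 4.41 to 660 ± 13.7 CPM (SD, n = 3 each), and the eosinophil receptor gene Ccr3 stood at 21.8 ± 0.292 and 21.6 ± 0.235 CPM (adjusted p = 0.918, edgeR). The mast cell and basophil genes Fcer1a, Ms4a2 and Hdc rose by 1.71, 0.79 and 1.15 on the log2 scale and Cpa3 rose from 7.93 ± 1.55 to 18.9 ± 1.99 CPM, while the protease gene Prss34 fell by 1.38 and Prss29 fell by 4.22. Among mitochondrially encoded genes Mt-nd6 and Mt-nd5 fell by 1.82 ± 0.0792 and 1.30 ± 0.0888 (log2 ± SE), and Mt-co1 rose by 0.21 ± 0.0326. Clock genes Per1, Nr1d1 and Dbp fell by 1.07, 0.80 and 0.60, and Arntl and the weakly expressed Npas2 rose by 1.15 and 1.68. Of 23 immediate early genes 10 rose and 5 fell: Fos, Junb and Dusp1 rose by 2.42, 1.59 and 1.60, Myc fell by 0.81, and Nr4a3, near the floor at 0.704 ± 0.143 and 0.0213 ± 0.0369 CPM, had the largest change, a fall of 4.83 ± 0.912. The heat shock gene Hspa1a rose by 2.00. The labels used here give no hour of collection and no interval between the last session and collection. In control 2 and loaded 2, 18 features lay at least 2-fold above both other libraries of their group, against 3 for replicate 1 and 3 for replicate 3. Most of the 18 are AABR and new-gene features, such as NewGene_359, 2.58 and 2.73 higher on the log2 scale.

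Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 5895 genes, 1084 at least 2-fold and 18 lists, and the highest of the others gave 1, 1 and 5. Only 1 split of the 10, the real one, reached each real value. Every other split puts control and loaded libraries in the same group. The difference between loaded and control then widens the spread within groups, so low gene counts were set beforehand. These counts do not measure what chance alone would call.

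Skeletal muscle genes were higher in loaded libraries. Choosing another of the scalings tried would not remove the rise: the lowest median over 3 other scalings was 1.14, with an SD over members of 0.357. That outcome was set beforehand, since with library totals the median over all tested genes moved only from 0.0039 to 0.0786. The SD is a spread between genes and not an error of the scaling. A lower marrow share that raised every other tissue alike is argued against. The muscle median exceeded that of 112 pooled genes of 8 other lists of tissues outside marrow by 0.85 (95% bootstrap interval over genes 0.469 to 1.04). The osteoblast and osteocyte list alone, however, had a median of 0.89. This set was put together after its values were seen, and the adipocyte list is left out because marrow holds adipocytes. The interval treats genes as independent and does not measure the spread between libraries. More muscle of 1 makeup, as the only source of these genes, would raise them by the same fold. The log2 fold changes of members differed by up to 1.36 with SEs of at most 0.072. If other cells add reads of some members, unequal folds could arise with 1 makeup too. More muscle in the loaded dissections, of 1 or of varying makeup, remains a candidate explanation. That 21 of 21 members rose and 0 fell restates the pattern, so it does not favour this explanation over others. An effect of loading on muscle already present was not tested.

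Interferon genes were higher in loaded libraries. Their median lay 1.01 above that of the B lymphocyte list, the highest of 4 leukocyte lists (95% bootstrap interval over genes 0.111 to 1.70). This argues against an even gain of monocytes, neutrophils, B or T cells as the whole cause. A gain of 1 subset could go unseen, since members of the monocyte list ranged from -1.13 to 1.54. The interval treats genes as independent and does not measure the spread between libraries. Cell types outside these lists stay open. The lowest median over 3 other scalings was 1.26, so choosing another of these scalings would not remove the rise. As for muscle, that outcome was set beforehand, since with library totals the median over all tested genes moved only from 0.0039 to 0.0786. A batch, housing or infection difference between the groups cannot be told apart from load, because 0 label fields give a batch, cage, day or run. A response to load stays open and was not tested apart from these.

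Col10a1 rose more than the other cartilage collagens. More cartilage of 1 makeup as the only source of the cartilage collagens is argued against. The log2 fold changes of the 7 collagens of the cartilage matrix list, which leaves out Col10a1, differed by up to 0.82 with SEs of at most 0.145. If other tissues in the libraries also express these collagens, more cartilage of 1 makeup could give unequal folds, which this test cannot exclude. This test was picked among several with the fold changes already known, and its bar is that of the muscle test (over 4 times the largest SE). More bone of 1 makeup as the only source of both genes is argued against as well, because Col10a1 rose by 0.45 more than Omd (combined SE 0.162). Omd is the osteoblast gene with the largest rise. Other sources of Omd could dampen its rise, so more bone is not excluded. Of the genes of the growth plate, 3 of 3 (Ihh, Panx3 and Pth1r) rose, but these were picked after their values were seen. In the whole hypertrophic list 9 of 14 rose, 2 (Alpl and Runx3) fell and 3, among them Mmp13, did not pass. More growth-plate cartilage in the loaded samples cannot be told apart from a change within chondrocytes, because the labels give no position of the dissection. A load-induced shift toward hypertrophy is therefore only a hypothesis here.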
